A study of Homo sapiens with 5 samples.

How the data were processed

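The series holds single-cell RNA libraries from H1 cells, an established human embryonic stem cell line. They were collected at D11, D14, D21, D32 and D39 of differentiation toward pancreatic islet cells. Whether they come from a single differentiation or from several is not given in the sources used here. The D21, D32 and D39 sample titles share a naming pattern that the D11 and D14 titles do not follow. Per the labels' protocols, aggregates were dissociated, live propidium iodide-negative cells were sorted, 10000 cells per sample were loaded, and libraries were made with a 10x Chromium 3' version 3.1 kit. The sequencers named are of the NextSeq, HiSeq and NovaSeq series, and the instrument of each library is not given in the sources used here. The title of the last sample says D39 while its day field says D32. It was taken as D39, because its barcodes carry the prefix D39.

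The deposited values are counts of unique molecular identifiers (UMIs) per cell and gene, with all 5 libraries merged by the authors into 1 matrix of 25686 cells and 32738 genes. Cell Ranger and the hg19 genome are named in the submitters' processing notes, and their versions and the annotation release are not given in the sources used here. The entries were checked to be whole numbers, and they sum to 359337112 UMIs, with 27312 genes holding at least 1 UMI. The cells had between 1095 and 9645 detected genes, at least 3164 UMIs, and at most 20.0% mitochondrial UMIs in any library. Which cell filters gave these limits, and whether doublets or free RNA had been removed, is not stated. Total depth per library ran from 22612478 to 153255811 UMIs and the number of cells from 2094 to 9713.

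Every deposited cell was used. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, ranked within each library, were reduced to 30 principal components, linked over 15 neighbours and grouped by the Leiden method at resolution 1, leaving out mitochondrial genes, ribosomal protein genes and every gene of the 15 readout lists, while the hormone genes INS, GCG and SST stayed in. Clusters were named from 96 markers of 14 cell types, of which 95 were in the matrix: pancreatic progenitor, endocrine progenitor, beta, alpha, delta, enterochromaffin, acinar, duct, mesenchyme, hepatocyte, intestinal or gastric epithelium, pluripotent, endothelium and neural crest or glia. A cluster took the name of the type whose markers had the highest mean log2 fold over the median cluster (20 CPM added) when that mean was at least 1, led the next type by at least 0.25, rested on at least 3 markers that were 2-fold higher, held at least 50 cells, had a median UMI total at most 1.5 times that of its library, and had no more markers of another type among the 10 genes of largest fold over the rest of its libraries (50 CPM added). These naming limits were set after the clusters had been seen; the markers, the gene lists, the comparisons, the rule for named genes and most alternatives were chosen before the data were examined. Clusters outside the limits stayed unnamed. A name ending in -like is a marker-based label and not a proof of cell identity.

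With 1 library per day there are no replicates, so no test between days or classes was run and no gene is called changed. UMIs were summed over all cells of a library, or over the cells of a class holding at least 50 cells, and given as CPM, the usual depth-scaled counts, with exact Poisson intervals. Ratios are log2 ratios of CPM after 0.5 counts were added to each sum, with exact conditional 95% intervals. Shares of cells have exact Clopper-Pearson 95% intervals, and for a share of 0 the limit given is 3 counts of the total. All of these cover counting error only, not the spread between cultures. Against a sum of 0 counts a fold was taken against a floor of 3 counts. The named genes are the 10 highest and 10 lowest ratios of each main comparison among genes with at least 50 CPM in either sum, leaving out mitochondrial, ribosomal protein, clone-named and LINC genes, plus members of the gene lists with large or small ratios; a gene named outside that rule was chosen after its values were seen. Some genes of the lists count in the medians but are not reported here by name.

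The 15 readout lists cover beta-cell maturation, secretion, vesicles and exocytosis, oxidative phosphorylation, glycolysis, hypoxia, endoplasmic reticulum (ER) stress, cholesterol synthesis, proliferation, Notch, YAP, immediate early and heat shock, circadian, oncofetal and gut transcription factor genes. A further 2 lists, pancreatic and endocrine transcription factors and hormones, were described in whole libraries only, because they share members with the markers. Of their 187 members 186 were in the matrix. Each list is given by its median log2 ratio and its number of members at least 2-fold higher or lower. Where it differs, the median is also given with the floor applied, which leaves out members at 3 counts or fewer in both sums and sets a remaining count of 0 to 3. Percentiles among 10000 random lists matched on mean CPM (within the nearest 100 genes) are given as a description of these libraries. Tested on simulated data with 100 altered genes per fold, 2-fold lists passed the 95th percentile in 100% of draws and 86.5% to 93% of unchanged lists lay between the 5th and 95th, where 90% would by chance. In the beta-like comparison of D39 with D21 98% of 2-fold genes but 77% of genes set 4-fold lower came within 0.5 of the true log2 ratio. Over the 4 simulated comparisons the 95% intervals held the true ratio for 94% to 97% of the altered genes. The simulated counts were independent Poisson draws around 1 shared profile, which is what the intervals assume. The simulation therefore checks the computation and not how real libraries differ.

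For hormone shares, each cell was thinned to 5500 UMIs, the largest multiple of 500 that at least 80% of the cells of each library reached, which left out 199, 1203, 110, 174 and 303 cells at D11, D14, D21, D32 and D39. A cell counted as positive when the hormone held at least 1% of its thinned UMIs. INS, IGF2 and their read-through transcript overlap on the genome, so their counts may be shared among these genes.

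Scrublet, run per library, called 763 doublets at D11, 0 at D14, 0 at D21, 4 at D32 and 8 at D39, with score thresholds from 0.161 to 0.604. The caller is taken as not having worked at D14, D21, D32 and D39, where it called under 0.5% of cells, so leaving out the highest 5% of doublet scores in each library was added as an alternative. Other alternatives changed the clustering resolution, the number of variable genes, joint against separate clustering of libraries, the naming limits, the cells of clusters 0 and 21, the scaling (median of ratios over genes with at least 20 counts), the low-count filter, the added count, the share that makes a cell positive and the thinning. A scaling by median of ratios would shift all ratios by more than 0.1 in some comparisons, and that shift is given where it applies. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9. Raw reads were not analysed here.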

Results

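Gene expression was compared across 5 days of H1 stem cell differentiation toward islet cells: D11, D14, D21, D32 and D39. The libraries held 9713, 8101, 3140, 2638 and 2094 cells in that order. Median depth was 13695 UMIs per cell at D11, 7416 at D14, 22015.5 at D21, 14043 at D32 and 10245.5 at D39, and the median mitochondrial share lay between 7.995% at D11 and 14.3% at D39. Each day had 1 library, so a difference between days cannot be told apart from a difference between cultures, sorts or sequencing runs. Values are CPM of summed UMIs, with ratios on the log2 scale.

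Pancreatic progenitors express PDX1 and SOX9, endocrine progenitors switch on NEUROG3 for a short time, and the hormone cells that follow include insulin-producing beta cells, glucagon-producing alpha cells and serotonin-producing enterochromaffin cells, a gut cell type that stem cell differentiations can also form. At D11 the pancreatic-progenitor-like class held 28.7% of cells (95% interval 27.8% to 29.6%) and the endocrine-progenitor-like class 16.5% (15.7% to 17.2%). That class (cluster 3) does not hold all cells with NEUROG3. Unnamed cluster 2, 25.8% of D11 cells, had NEUROG3 at 213 CPM and PAX4 at 283, against 419 and 321 in cluster 3. Its SOX4 was lower, at 371 against 1594 CPM. The D11 pancreatic-progenitor-like share depended on the grouping, at 15.9% with a clustering resolution of 0.5 and 15.2% when each library was clustered alone. No cell of D11 fell in an alpha-like, beta-like or enterochromaffin-like cluster, 0 of 9713 cells, which by counting alone allows up to 0.0309%. Most clusters held cells almost wholly from 1 library or from D32 and D39, so the grouping partly sets this 0. After thinning, 24 of 9514 D11 cells were INS-positive and 4 were GCG-positive. At D14 an alpha-like class held 27.7% (26.8% to 28.7%), the endocrine-progenitor-like class 20.6% (19.7% to 21.5%) and the pancreatic-progenitor-like class 11.7% (10.998% to 12.4%). Beta-like cells made up 18.98% of D21 (17.6% to 20.4%), 15.5% of D32 (14.1% to 16.9%) and 10.8% of D39 (9.54% to 12.3%). The enterochromaffin-like class held 785 of 3140 cells at D21 (23.5% to 26.6%), 25.2% at D32 (23.5% to 26.9%) and 17.1% at D39 (15.6% to 18.8%). Alpha-like cells were 0.223% of D21, 40.5% of D32 (38.6% to 42.4%) and 58.9% of D39 (56.7% to 61.0%). Unnamed clusters took 54.8%, 40.0%, 54.9%, 18.4% and 12.9% of the 5 libraries in day order. The low D21 alpha-like share goes with 1 such cluster, cluster 16, which held 26.7% of D21 cells and scored best for alpha markers with delta markers close behind. Cluster 15, 17.8% of D21 cells, scored best for enterochromaffin markers and is also outside the limits, so the D21 enterochromaffin-like share depends on them too.

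**Figure D1:**
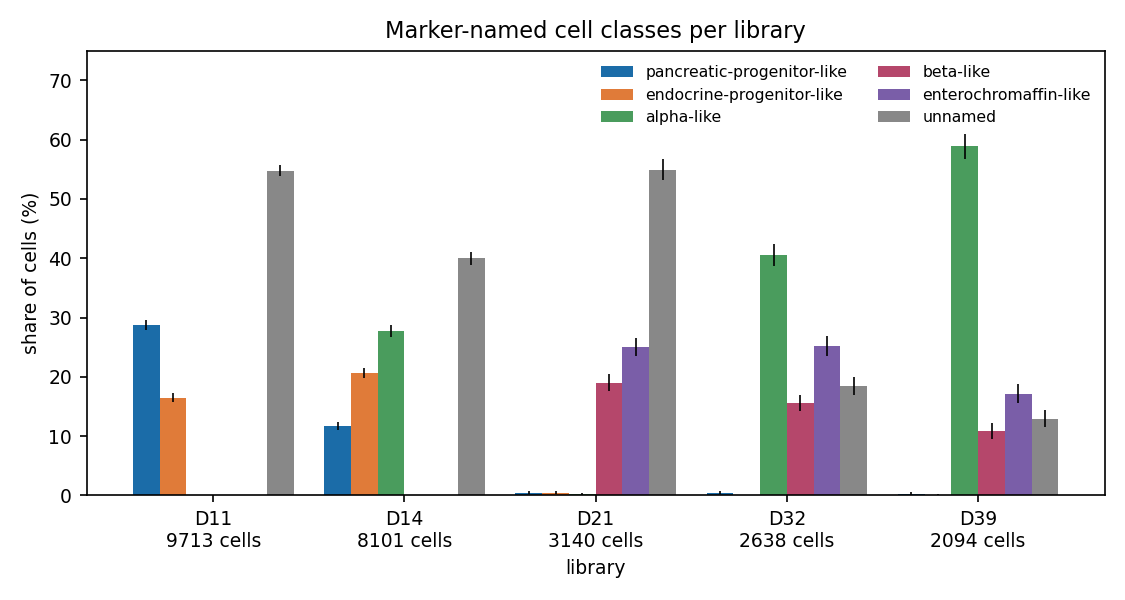
Share of cells (percent, vertical axis) of each library by cell class, with exact 95% intervals as error bars. The alpha-like share is 0.223% at D21 and 58.9% at D39, while the beta-like share is 18.98% at D21 and 10.8% at D39; cluster 16, 26.7% of D21 with alpha as its best score, is among the unnamed cells under limits set after the clusters were seen.

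At D11 the endocrine-progenitor-like cells (cluster 3) were set against the pancreatic-progenitor-like cells (almost all in clusters 0 and 6) of the same library. Endocrine commitment is known to end the cell cycle, to shut Notch signalling, which keeps progenitors undecided, and YAP, which drives their growth, and to switch on the machinery of hormone granules. All 15 vesicle and exocytosis genes were at least 2-fold higher in the endocrine-progenitor-like cells, with a median of 3.89. Chromogranin CHGA, the main granule protein, stood at 14186 against 365 CPM, and secretogranin SCG2 was higher by 5.85 (5.74 to 5.95). The secretion list had a median of 2.27, with 10 of 14 members at least 2-fold higher. All 20 proliferation genes were at least 2-fold lower, with a median of −5.51, and MKI67 was at 1.23 against 160.5 CPM; cell cycle genes lead cluster 0, and without it the median was −1.72, with 19 of 20 genes at least 2-fold lower. In the Notch list 7 of 10 genes were at least 2-fold lower, among them the target HES1 at −5.28 and NOTCH1 at −4.40, while the ligand DLL4 was higher at 2.88 and DLL1 lay near even at −0.14. The YAP list had a median of −4.62, with YAP1 itself at 2.81 against 80.5 CPM and its target CYR61 at −5.87. ER stress genes had a median of 0.73 and cholesterol synthesis genes 0.58. At D14 the same pair of classes (almost all in clusters 11 and 4) had medians of 1.89 for vesicle genes, −4.13 for proliferation, −3.29 for Notch and −4.83 for YAP (−3.22 with the floor applied). Cholesterol synthesis was higher there too, at 1.21 with 9 of 12 genes at least 2-fold higher. A median-of-ratios scaling would move the D14 values by −0.11.

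Among the 10 highest ratios of D14 over D11 were INS and GCG, which encode insulin and proglucagon, the zinc transporter SLC30A8 of insulin granules, the potassium channel KCNMA1, the beta-cell protein C2CD4A and the chemokine CXCL12. Among the 10 lowest were the adhesion protein VTN, the Wnt antagonist FRZB, the keratin KRT18 and the digestive enzyme gene PRSS1. GCG stood at 6100.3 CPM at D14 against 8.26 at D11, a ratio of 9.53 (9.45 to 9.61). INS was at 9297 against 136 CPM, 68.1-fold higher, and SLC30A8 at 158 against 0.163. The glutamate receptor gene GRIN3A had the highest ratio, 11.12 (10.12 to 12.69). C2CD4A was 205-fold higher, CXCL12 142-fold, KCNMA1 91.3-fold, the nuclear receptor NR0B1 70.5-fold, PCP4 58.1-fold and the collagen COL5A2 51.0-fold. VTN was 39.8-fold lower, at 13.1 against 521 CPM, and KRT18 15.2-fold lower, at 73.2 against 1112. Growth factor PTN was 22.9-fold lower, FRZB 21.8-fold, CPVL 18.6-fold, SERPINF1 17.7-fold, LYPD1 17.6-fold and ANXA2 15.8-fold. PRSS1 was at 11.7 against 222 CPM and FBLN1 at 11.7 against 164. Median-of-ratios scaling would lower the ratios of this comparison by a further 0.22, so medians near 0 carry no direction.

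Transcription factors of islet identity were among the genes higher at D14: 12 of 25 were at least 2-fold higher and 4 lower, with a median of 0.87. ISL1 stood at 231 against 8.78 CPM, PAX6 at 208 against 13.8, and the beta-cell factor NKX6-1 at 187 against 11.3. LMX1A, which directs serotonin cells, had a ratio of 5.45. The progenitor factors SOX9 (−1.61), PTF1A (−1.78) and HHEX (−3.40) were lower. In the secretion list 13 of 14 genes were at least 2-fold higher, with a median of 2.59, including the sulfonylurea receptor ABCC8 at 97.8 against 3.52 CPM, its partner KCNJ11 at 4.10 and the prohormone convertase PCSK2 at 4.25. The maturation list had a median of 3.92, although UCN3 and G6PC2 were under 3 CPM on both days, and hormones had 3.52 (3.33 with the floor applied), with IAPP lower at −4.54. The vesicle list had 1.06, with the fusion protein STX1A at 2.90 and SYT7 at 2.53, and SCG2 lower at −1.19. Cholesterol synthesis had 1.25, with HMGCS1 at 608 against 159 CPM. Proliferation had −2.67, with 19 of 20 genes at least 2-fold lower and TOP2A at 11.7 against 86.2 CPM. Cell cycle genes lead cluster 0, 16.8% of D11 cells and 1 cell of D14, where TOP2A was at 361 CPM. Much of the D11 level thus lies in that cluster, and the whole-library median without it was not computed. Notch (−1.37, HES1 −2.34) and YAP (−1.39, ANKRD1 −5.20) were lower, and so were glycolysis (−1.07), with ENO1 at −2.02 and GAPDH at −1.80, and oxidative phosphorylation (−0.81), with ATP5B at −2.11. Gut transcription factors had a median of 1.37, with HNF4A at 83.6 against 29.0 CPM. Smaller medians were circadian 0.78, ER stress 0.47, immediate early and heat shock 0.31, oncofetal −0.14 and hypoxia −0.02. Against matched random lists the medians of ER stress, immediate early, oncofetal and hypoxia genes lay between the 5th and 95th percentiles and those of all other lists outside.

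Marker genes of cell types that a mixed culture can hold were followed in the same pair of libraries. Acinar markers had a median of −1.49, hepatocyte markers −0.97, with SERPINA1 at 118 against 1159.7 CPM, and pancreatic progenitor markers −1.18. Alpha markers had 1.41, enterochromaffin markers 1.39, beta markers 1.16, delta markers 0.61 and endocrine progenitor markers 0.15. Duct markers had a median of 0.14, although KRT19 was lower at −2.33, and mesenchyme markers had −0.87, with collagens COL1A1 and COL3A1 under 7 CPM on both days. Pluripotency markers had −0.18, and POU5F1 stood at 0.117 and 0.137 CPM at D14 and D11. Intestinal or gastric markers had −0.42, or −2.28 with the floor applied. Endothelial markers had 3.84, with CLDN5 the most abundant at 42.1 against 3.06 CPM, a gene among the top 10 of the D14 endocrine-progenitor-like cluster, and neural crest markers had 1.82, with SOX10 at 1.70 CPM.

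Within classes, the pancreatic-progenitor-like cells of D14 (947 cells, 944 of them in cluster 4) were compared with those of D11 (2791 cells, almost all in clusters 0 and 6). These clusters each come mostly from 1 library. Progenitors are not known to release hormone, yet 12 of 14 secretion genes were at least 2-fold higher, with a median of 2.80, and 13 of 15 vesicle genes, with a median of 2.53. CHGA stood at 1700.1 against 365 CPM and ABCC8 at 22.6 against 1.28. Of 751 thinned D14 cells in the class, 64.3% had at least 1 INS UMI against 1.92% at D11, with a median of 1 INS UMI. RNA released by other cells is an open source of a part of these counts. Proliferation was lower in the class, at −1.54 with 17 of 20 genes at least 2-fold lower, CDK1 at −2.36 and TOP2A at −1.58. The D11 TOP2A counts lie almost wholly in cluster 0, which cell cycle genes lead: 11722 UMIs with it and 165 without. Without cluster 0 the median was 1.41, and TOP2A stood at 86.3 against 12.7 CPM. That step takes cycling cells from D11 only, while D14 keeps its own, so the turned median carries no direction. Gut transcription factors were higher, at 1.25. In the endocrine-progenitor-like cells (cluster 11 over cluster 3) the secretion median was 2.04, with PCSK2 at 79.3 against 4.35 CPM and SLC30A8 at 54.3 CPM against 1 count at D11, a ratio of 9.47 (7.57 to 15.36). Cholesterol synthesis had 1.18, with INSIG1 at 1.60, glycolysis −1.13, with PFKP at −2.08 and ALDOA at −1.90, and proliferation −1.09. The scaling shift is −0.14 for the pancreatic-progenitor-like and −0.22 for the endocrine-progenitor-like comparison.

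Among the 10 highest ratios of D21 over D14 were SST, which encodes somatostatin, TPH1, the enzyme that starts serotonin synthesis, the gut hormone NTS, the interferon-induced IFI6, the mucosal protein AGR2, the transport protein TTR of islet cells, the prohormone convertase PCSK1, which cuts proinsulin, and the incretin-degrading enzyme DPP4. Among the 10 lowest were the translational repressor NANOS1, the complement gene C7, the neurotrophic factor METRN and the signalling feedback genes DUSP5 and PHLDA1. SST stood at 1122 against 15.2 CPM, 74.0-fold higher, and TPH1 at 1309 against 40.8, 32.1-fold higher. NTS was at 122 against 4.68 CPM, and IFI6 was 11.8-fold higher, AGR2 9.98-fold, LGALS3BP 8.53-fold and DPP4 9.11-fold. TTR was at 7007 against 729 CPM, PCSK1 at 209 against 22.7 and the chaperone CLU at 441 against 51.9. NANOS1 was 11.3-fold lower, MUC12 10.1-fold, C1orf194 9.82-fold, C7 9.43-fold, and METRN was at 146 against 1163 CPM. The non-coding HOTAIRM1 was 6.73-fold lower, DUSP5 6.68-fold, PHLDA1 5.91-fold, PODXL 5.28-fold and SMIM5 5.11-fold. The hormone list had a median of 4.91, with 8 of 9 members at least 2-fold higher, among them INS (1.73), GCG (1.84) and PYY (4.91), and IAPP, the peptide that beta cells release with insulin, at 38.1 against 0.264 CPM. Maturation had 1.10, with ENTPD3 at 5.18 and MAFA at 8.79 CPM, secretion 0.69, with ABCC8 at 1.40, glycolysis 0.48, with PFKP at 1.63, and ER stress 0.33. Notch (−0.80; NRARP −2.14), proliferation (−0.65) and hypoxia (−0.48) were lower. Against matched random lists the medians of maturation, secretion, vesicle, glycolysis, ER stress and hormone genes lay above the 95th percentile, those of hypoxia, proliferation and Notch genes below the 5th, and all others between. Islet transcription factors had a median of −0.03, with ISL1 at 461 against 231 CPM and NEUROG3 at 25.4 against 90.5. Gut transcription factors (0.31; HNF4G 1.05), vesicle genes (0.30) and immediate early genes (0.24) had small positive medians, and those of oxidative phosphorylation (0.04) and cholesterol synthesis (0.06) were near 0.

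Early human endocrine cells can carry insulin and glucagon together, unlike adult beta or alpha cells. After thinning, 22.9% of D21 cells were positive for both INS and GCG (21.4% to 24.4%), 694 of 3030 cells, while 1146 had INS without GCG and 24 had GCG without INS. The share of double-positive cells was 11.1% at D14 (10.3% to 11.8%), 25.8% at D32 (24.1% to 27.6%) and 13.6% at D39 (12.0% to 15.2%), and 0 of 9514 cells at D11. At D21, 71.7% of cluster 16 (68.5% to 74.8%) was double-positive, against 1.75% of beta-like cells (0.843% to 3.20%), a class of similar depth with a median of 22554 UMIs against 23675. INS, GCG and SST were among the clustering genes, so such differences between clusters are partly built in. Enterochromaffin-like cells of D21 had 12.0% (9.82% to 14.6%), cluster 10 had 3.27% and cluster 15 had 0 of 547 cells. At D14 the alpha-like class had 37.1% double-positive cells at a median of 7084 UMIs. It was INS-positive in 58.5% and GCG-positive in 58.1%, and of INS, GCG and SST 21.5% held INS only and 21.1% GCG only. The pancreatic-progenitor-like class of D14, which is not known to make either hormone, had 0.932% double-positive cells at 8323 UMIs, whose source was not tested. Alpha-like cells were INS-positive in 75.8% at D32 and 30.6% at D39 (27.8% to 33.5%), and double-positive in 56.1% (53.0% to 59.2%) and 21.4% (18.96% to 24.0%). The enterochromaffin-like class was INS-positive in 53.9% at D21, 4.03% at D32 and 0.627% at D39. SST-positive cells were 2.28% of D21, 3.90% of D32 and 2.46% of D39. Set against beta-like cells, cluster 16 had lower PCSK1 (61.8 against 607 CPM), lower MAFA (−3.40), ENTPD3 (−2.94) and ISX (−2.07), higher UCN3 (4.01), a maturation median of −0.30 and an ER stress median of 0.42, where median-of-ratios scaling would add 0.24.

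**Figure D2:**
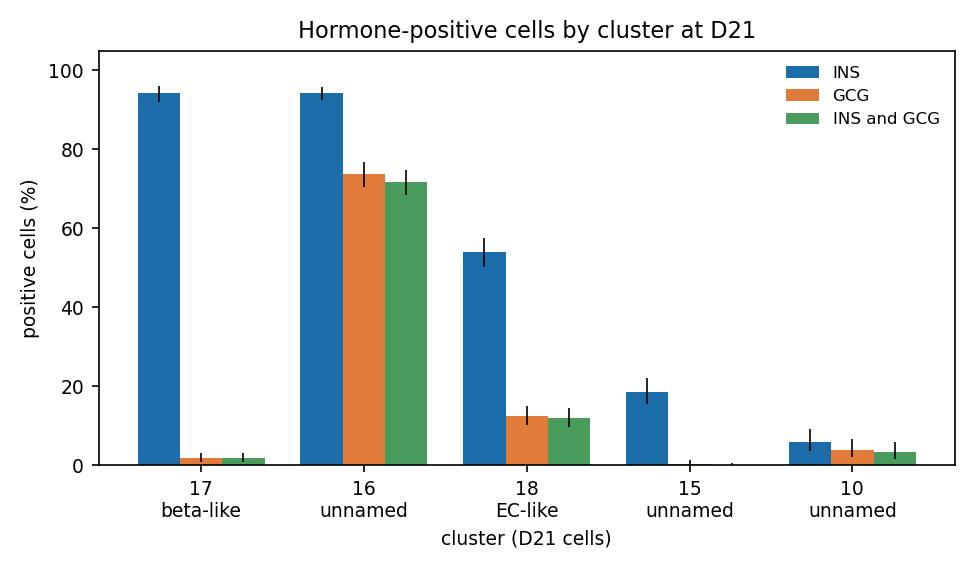
Percent of D21 cells (vertical axis) positive for INS, for GCG and for both after thinning to 5500 UMIs, by cluster, with exact 95% intervals. Cluster 16 has 71.7% double-positive cells and the beta-like cluster 1.75%; INS and GCG were among the genes used to form the clusters.

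At D32, genes that respond within minutes to a stimulus, the neuropeptide NPW and the beta-cell peptide IAPP were higher than at D21, while the hormone genes GAST (gastrin), GAL (galanin) and PTHLH, the growth factor IGF2 and the lipoprotein APOA2 were lower. NPW stood at 95.7 against 1.87 CPM, 51.1-fold higher. Nuclear receptor NR4A1 was 23.7-fold higher and FOSB was at 199 against 12.2 CPM. IAPP was at 398 against 38.1 CPM, the synapse organiser CBLN4 11.1-fold higher, the vitamin D carrier GC of alpha cells 10.5-fold, HABP2 7.60-fold and the BMP target ID1 7.32-fold. Uroguanylin GUCA2B was at 272 against 19.3 CPM. Summed over the libraries of each cluster it was at 25319 CPM in cluster 20, 24 cells of D32 and 12 of D39, against 36.0 CPM in cluster 7, mostly cells of the same 2 days. MTRNR2L2 was 13.7-fold higher, but it is a near copy of a mitochondrial ribosomal RNA and its reads may come from there. PTHLH was 39.3-fold lower, GAST was at 5.41 against 189 CPM, CHODL was 32.6-fold lower, COL2A1 29.5-fold, GAL 25.2-fold, CRISPLD1 21.4-fold, GSTA1 18.4-fold and TNFRSF21 10.5-fold. IGF2 was at 61.2 against 1058 CPM and APOA2 at 49.5 against 778.

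The immediate early and heat shock list had a median of 1.81, with 8 of 13 members at least 2-fold higher, FOS at 436 against 69.7 CPM, JUNB at 195 against 27.6 and EGR1 at 342 against 65.9, while HSPA1B (−0.23) was slightly lower. Within beta-like cells the list had 1.68 and within enterochromaffin-like cells 1.58. Clock genes were higher, at a median of 0.52, led by PER3 at 24.1 against 4.42 CPM, BHLHE41 (1.89) and PER1 (1.26), with DBP lower (−1.16). Proliferation had a median of 1.28, with TOP2A at 33.9 against 7.12 CPM and RRM2 at 3.16, though the replication gene MCM2 was lower at −1.61. The 37 D32 cells of cluster 21, which cell cycle genes lead, held most of these counts: TOP2A had 1346 UMIs with them and 216 without. Without these cells the median was −0.44 and TOP2A at 5.52 CPM. The cluster holds 0 of 3140 D21 cells, so that step takes cycling cells from D32 only and carries no direction. The endocrine progenitor markers had −1.27, with NEUROG3 at 1.56 against 25.4 CPM and SOX4 at −2.04. Islet transcription factors had −0.62, with 8 of 25 at least 2-fold lower, among them INSM1 (−1.58), NKX6-1 (−1.22) and PDX1 (−1.06), and gut transcription factors had −1.14, with CDX2 at −1.88. The oncofetal list had −0.85, with LIN28B, a fetal RNA-binding protein, at −1.35, Notch −0.75, although HES1 was higher at 1.24, and YAP −0.46, with YAP1 at 1.66 against 30.6 CPM. Hormones had −0.37, with SST at 1.34 and TPH1 at −1.44. CHGA (1.37) and VGF (2.37) were higher in a vesicle list whose median was 0.15. Maturation (−0.21) split, with MAFA (−3.11) and G6PC2 (−3.22) lower and SIX2 (1.77) and CHGB (1.57) higher. Cholesterol synthesis had −0.29, secretion 0.16, glycolysis 0.09, oxidative phosphorylation 0.06, hypoxia 0.04 and ER stress −0.01. Against matched random lists the medians of maturation, oxidative phosphorylation, glycolysis, hypoxia, ER stress, YAP and hormone genes lay between the 5th and 95th percentiles and the others outside.

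D39 differed less from D32. The beta-cell peptide IAPP and the neuropeptide NPW were higher again, insulin and the immediate early genes were lower, and several of the most extreme genes were non-coding or general cell genes. IAPP stood at 887 against 398 CPM and NPW at 185 against 95.7. The transport protein ARF5 was 4.30-fold higher, ZFP36L1 2.44-fold, the cytokine MIF 2.27-fold, SERF2 2.24-fold, VSTM2L 2.01-fold, MAZ 1.97-fold and the antioxidant enzyme GPX1 1.94-fold. PPP1R1A, a phosphatase inhibitor of beta cells, was at 285 against 142 CPM. INS had a ratio of −1.13, PYY of −2.15 and TPH1 of −0.82, whereas GCG was higher at 0.36, and the hormone list had a median of −0.82. The immediate early list had a median of −0.68, with NR4A1 at 25.4 against 74.1 CPM, FOSB 2.90-fold lower, FOS at −1.20 and ATF3 at −2.03. In alpha-like, beta-like and enterochromaffin-like cells the list had medians of −0.71, −0.73 and −0.94. The antibacterial enzyme LYZ was 7.60-fold lower, AMBP 4.21-fold, IGF2 2.87-fold and the histone gene HIST1H4C 2.79-fold. LYZ is among the top genes of cluster 20, 24 cells of D32 and 12 of D39, so its ratio may rest on few cells. The non-coding 7SK-2 (11.5-fold lower) and RN7SL1 (4.11-fold) and the mitochondrial near copies MTRNR2L2 (11.3-fold) and MTRNR2L12 (3.25-fold) have other copies in the genome, so their values are uncertain. The medians of the other readout lists lay between −0.41 for YAP (−0.18 with the floor applied) and 0.12 for vesicle genes. Only immediate early, oncofetal and hormone genes lay below the 5th percentile of matched random lists, and none above the 95th.

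INS stood at 30819 CPM at D21 and 13239 CPM at D39, a log2 ratio of −1.22 (−1.22 to −1.21), with a scaling shift of 0.10. Over the same days GCG had a ratio of 0.23 and IAPP of 4.54. The beta-like share of cells was lower at D39 and the alpha-like share higher, so the whole-library INS ratio mixes cell shares with levels per cell. Unnamed cluster 16, 26.7% of D21 cells, had INS at 67543 CPM, above the D21 beta-like level, and held 0 of 2094 cells at D39. Much of the D21 INS thus lay outside the beta-like class. Within beta-like cells INS was higher at D39, at 48534 against 31248 CPM at D21, and it was among the clustering genes. The beta-like cells of D32 and D39 together (cluster 19) had INS at 65306 CPM, so the D39 level lay below that of D32.

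**Figure D3:**
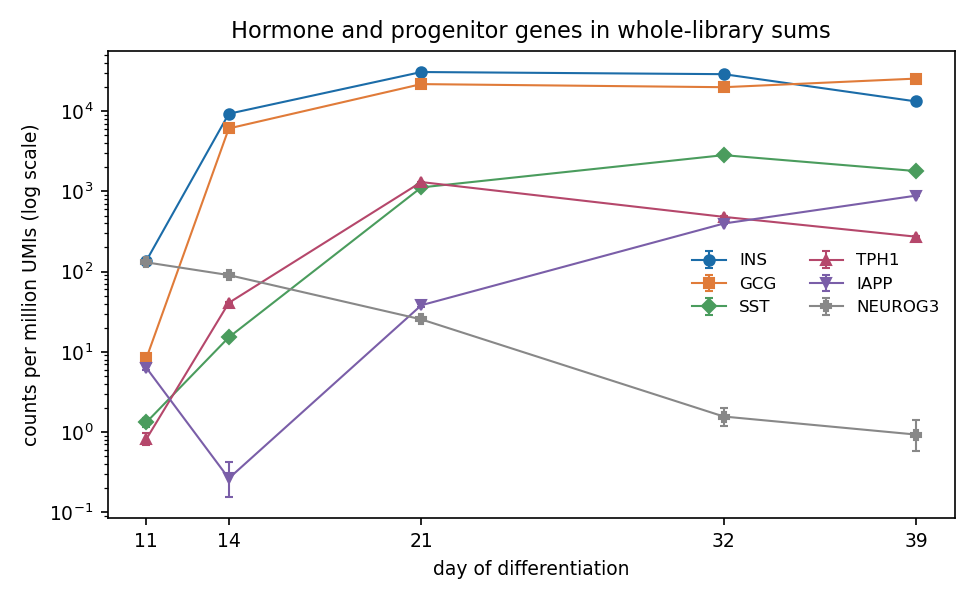
CPM in whole-library sums (vertical axis, log scale) of INS, GCG, SST, TPH1, IAPP and NEUROG3 by day of differentiation. IAPP goes from 38.1 CPM at D21 to 887 CPM at D39 and NEUROG3 from 90.5 CPM at D14 to 1.56 CPM at D32.

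Beta-like cells of D39 (cluster 19, 227 cells) were compared with those of D21 (cluster 17, 596 cells), which no cell of the other day joined. Genes higher at D39 include the beta-cell peptide IAPP, the maturation factor SIX2, which acts in human beta cells, the serotonin transporter SLC6A4 and the sodium-calcium exchanger SLC8A2, and genes lower include the growth factor IGF2, the lipoprotein APOA2 and the nicotinic receptor CHRNA3, which is among the top genes of cluster 17. IAPP stood at 6653 against 107 CPM, though it helped to define cluster 19. SIX2, which took no part in clustering, was at 104 against 6.69 CPM. ID1 was 108-fold higher, NPW 96.6-fold, SAMD11 68.6-fold, the matrix protein MFAP4 44.2-fold, TMEM130 27.9-fold, SLC6A4 13.5-fold, ELMO1 11.3-fold and SLC8A2 9.96-fold. APOA2 was at 1.74 against 645 CPM, IGF2 at 16.4 against 694, and GAST had 1 count at D39, a ratio of −6.71 (−12.60 to −4.82). CHODL was 59.9-fold lower, CHRNA3 23.3-fold, CXCL12 22.9-fold, GAL 21.7-fold, PLCE1 16.9-fold, C2CD4A 14.6-fold and TGFB2 13.1-fold.

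The maturation list in these beta-like cells had a median of −0.68 (−1.09 to −0.42 over resampled counts), or −0.77 with the floor applied, and its members parted. MAFA, the factor that drives adult insulin expression, stood at 1.39 against 33.4 CPM, G6PC2 was lower at −2.03 (−2.77 to −1.43) and ENTPD3 at −0.68, while CHGB was higher at 0.64. The adult beta-cell hormone gene UCN3 had 1 count at D39 and 4 at D21. The secretion list had a median of 0.29, with the incretin receptor GIPR higher at 194 against 68.4 CPM, but PCSK2 (50.9 against 197 CPM) and SLC30A8 (229 against 845 CPM) lower. All 12 cholesterol synthesis genes were lower, with a median of −0.78, DHCR7 at −1.59 and SQLE at 189 against 450.0 CPM. Immediate early genes had 0.95, with JUNB at 2.31, gut transcription factors −0.86, with the intestinal factor ISX at 31.0 against 59.9 CPM, and oxidative phosphorylation −0.31. Proliferation had 0.68, oncofetal −0.47, hypoxia 0.35 (0.17 with the floor applied), glycolysis 0.32, circadian 0.30, ER stress 0.28, Notch −0.11, YAP −0.03 (−0.47 with the floor applied) and vesicle genes 0.01. Against matched random lists the medians of secretion, glycolysis, ER stress, proliferation and immediate early genes lay above the 95th percentile, those of maturation, cholesterol synthesis and gut transcription factors below the 5th, and the others between.

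Enterochromaffin-like cells of D39 (cluster 9, 359 cells) and D21 (cluster 18, 785 cells) also lay in separate clusters. Higher at D39 were the neuropeptide genes NPW and ADCYAP1, the synaptic genes CBLN4 and LAMP5 and the homeodomain gene HOPX, and lower were the thyroid hormone-inactivating enzyme DIO3 and IGF2, among others. NPW stood at 255 against 1.86 CPM, TMEM130 was 69.5-fold higher, ID1 62.7-fold, SNTG1 35.3-fold, HOPX 31.0-fold, LAMP5 26.9-fold, ADCYAP1 24.3-fold, the protease HTRA1 19.4-fold, CBLN4 12.9-fold and VSTM2A 12.6-fold. DIO3 had 0 counts at D39 against 90.6 CPM, at least 119-fold lower, and GAST 0 counts, at least 87.9-fold lower. IGF2 had 1 count, a ratio of −9.32 (−15.21 to −7.43), and APOA2 3 counts, −8.71 (−11.21 to −7.38). CRISPLD1, a gene of cluster 18, was at 15.8 against 730.4 CPM, the BMP ligand GDF6 was 63.8-fold lower, SLITRK2 37.7-fold, PLCE1 37.2-fold, NR0B1 33.8-fold and PTHLH 31.9-fold. Oxidative phosphorylation was higher, with a median of 0.55, ATP5G1 at 1.06 and NDUFB2 at 420.5 against 217 CPM. Clock genes had 0.91, with PER3 at 32.6 against 4.94 CPM, BHLHE41 at 2.08 and TEF at 1.71, and immediate early genes 0.92, with FOSB at 2.49. The YAP list had −1.58, with AMOTL1 at −1.77 (−3.09 to −0.84) and every member but TEAD1 under 8 CPM, and the oncofetal list −0.79, with LIN28B at 3.31 against 19.4 CPM. Proliferation had 0.54, gut transcription factors −0.69 (−1.04 with the floor applied), hypoxia −0.53, with ADM at −1.19, secretion 0.29, vesicle genes 0.27, Notch −0.28, glycolysis 0.19, cholesterol synthesis 0.07, ER stress −0.07 and maturation 0.13 (−0.04 with the floor applied). Secretion, oxidative phosphorylation, immediate early and circadian genes lay above the 95th percentile of matched random lists, hypoxia, YAP, oncofetal and gut transcription factor genes below the 5th, and the others between.

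**Figure D4:**
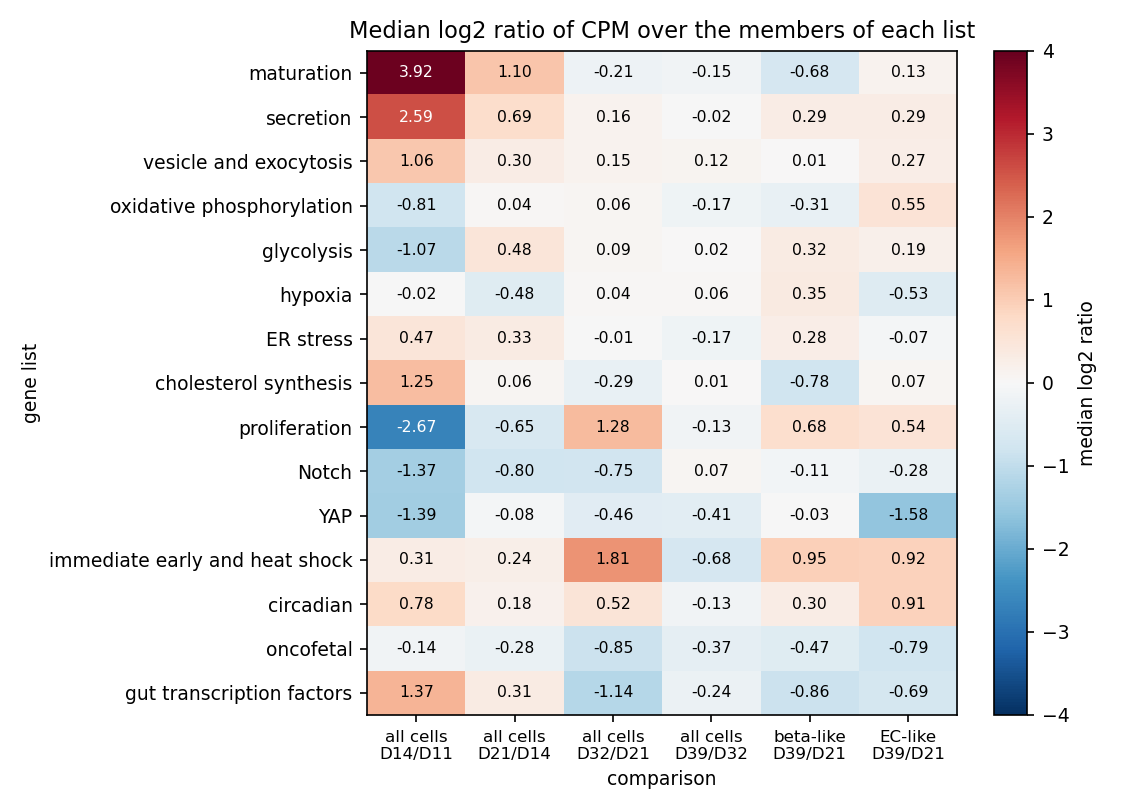
Median log2 ratio (colour) of each of the 15 readout lists (vertical axis) in 6 comparisons (horizontal axis). The proliferation list is at −2.67 in D14 over D11, where cell cycle genes lead cluster 0, 16.8% of D11 cells. The immediate early and heat shock list is at 1.81 in D32 over D21.

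Beta-like and enterochromaffin-like cells arise side by side in these cultures, and both dock and release granules, and in beta cells the channel subunit ABCC8 helps to couple release to glucose while SLC30A8 loads zinc into granules. At D39 the secretion list was higher in beta-like cells, with a median of 0.42 (0.26 to 0.62 over resampled counts), and the medians at D21 and D32 were 0.24 and 0.18, the same sign in all 3 libraries. SLC30A8 was higher in each, at 1.82, 1.94 and 1.52 in day order. ABCC8 was at 0.17 at D21 and 368 against 176 CPM at D39. PCSK2 was higher in beta-like cells at D21 (1.45) and lower at D39 (50.9 against 102 CPM), and the GLP-1 receptor gene GLP1R stood at −1.22 (−2.46 to −0.22) at D39. Maturation genes had medians of 1.29, 1.46 and 1.63, or 2.43, 1.87 and 1.63 with the floor applied. ENTPD3 carried part of that at D39, with 35.9 against 3.06 CPM, whereas CHGB was lower at −0.88. ER stress genes, which secretory load raises, had 0.44, 1.03 and 0.80, with the chaperone HSPA5 at 662 against 219 CPM at D39, PDIA4 at 1.84 and XBP1 at 1.58. Clock genes were lower in beta-like cells, at −0.33, −0.81 and −0.70, with BHLHE41 at −1.92 and NR1D1 at −1.71 at D39. Oxidative phosphorylation had 0.25 at D21 and −0.66 at D39, so its sign differs between the days. At D39 the medians of maturation, secretion, ER stress and oncofetal genes lay above the 95th percentile of matched random lists and those of oxidative phosphorylation, glycolysis and circadian genes below the 5th. The scaling shift is 0.11 at D32.

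**Figure D5:**
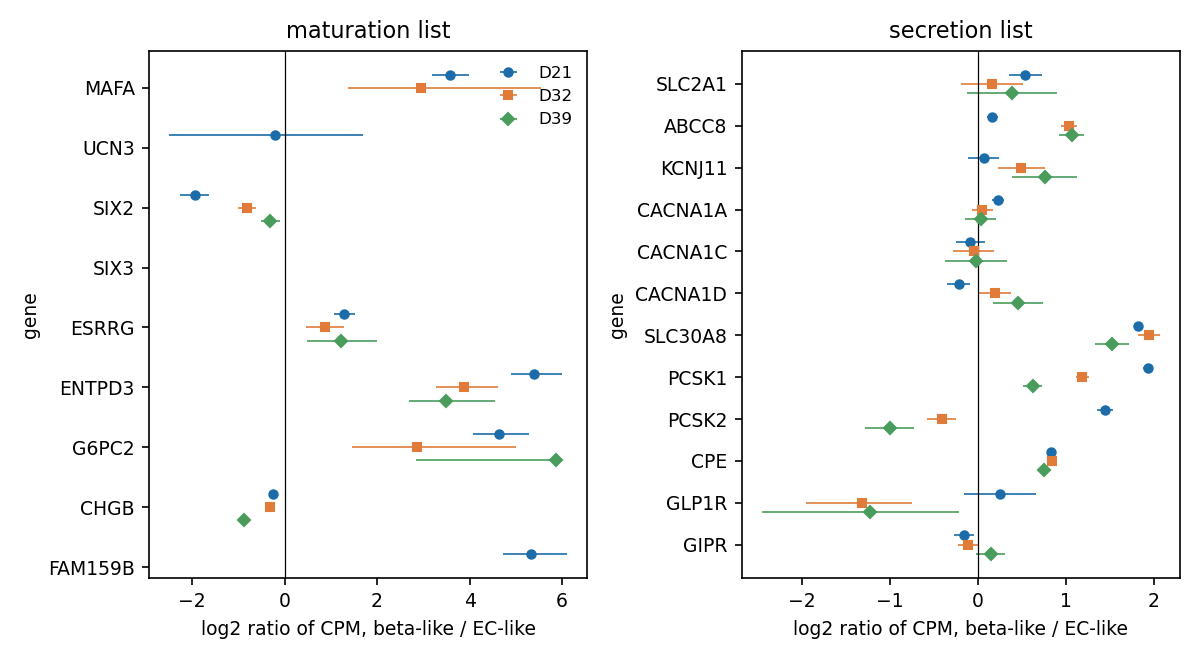
Log2 ratio of CPM in beta-like over enterochromaffin-like cells (horizontal axis) for maturation and secretion genes at D21, D32 and D39, with exact 95% counting intervals where bounded; genes with under 10 UMIs in the sums are not drawn. SLC30A8 lies at 1.82, 1.94 and 1.52.

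Alpha-like cells were the largest class at D39. Against them, D39 beta-like cells had a maturation median of 1.69 (1.22 with the floor applied), with SIX2 at 104 against 3.29 CPM, G6PC2 at 3.68 and the nuclear receptor gene ESRRG lower at −1.32. ER stress genes had 0.64 at D39 and 0.60 at D32, with DNAJB9 at 1.47 and HERPUD1 at 0.97. Proliferation genes were lower in beta-like cells at both days, at −3.59 and −3.43 (−2.85 with the floor applied), with TOP2A at 1.39 against 42.6 CPM at D39. That contrast lies in cluster 21, 63 alpha-like cells led by cell cycle genes, and without it the medians were −0.10 on both days (−0.16 at D32 and 0.04 at D39 with the floor applied), with alpha-like TOP2A at 2.18 CPM at D39. The scaling shift here is −0.16 at D32 and −0.18 at D39. Alpha-like cells of D39 over those of D14 (cluster 13) had a proliferation median of 2.75, with MKI67 at 18.3 against 0.314 CPM, or 0.84 without the 26 D39 cells of cluster 21, an immediate early median of 1.68 and a glycolysis median of 0.59. Maturation had −2.85 (−1.80 with the floor applied), with G6PC2 at −3.95 and UCN3 at 0.782 against 6.97 CPM but CHGB higher at 2.12; the shift is 0.16.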

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

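The hypoxia list of D39 over D21 stood out because beta-like and enterochromaffin-like cells went opposite ways: the median log2 ratio was 0.35 in beta-like cells and −0.53 in enterochromaffin-like cells, 0.874 apart. The difference was not tested, since each day had 1 library, and no test was chosen for it. With the floor applied the beta-like median was 0.17, and with a median-of-ratios scaling the medians were 0.42 and −0.55. Members did not all part: NDRG1 was higher at D39 in both classes, by 1.32 and 0.73, ANKRD37 was higher in both, by 1.54 and 1.23, and VEGFA was lower in both, by −0.53 and −0.42.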

How the results depend on the processing

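Of 65 alternatives 35 left a value within its main interval, 28 moved it further and 2 turned its direction. The alternatives without the top 5% of doublet scores, without naming limits and without cluster 0 or 21 were added after the data had been seen. The pancreatic-progenitor-like share of D11, 28.7%, was 15.9% at resolution 0.5, 21.2% at 2.0, 31.6% with 4000 variable genes, 30.1% without Scrublet calls, 15.2% with each library clustered alone, 30.1% without the top doublet scores and 36.3% without naming limits. The endocrine-progenitor-like share of D14, 20.6%, was 14.1% at resolution 2.0, 22.7% with 4000 genes, 17.8% without Scrublet calls, 18.02% with libraries alone and 27.3% without naming limits. At D39 the alpha-like share, 58.9%, was 67.0% at resolution 0.5, 62.3% with 4000 genes and 62.6% without Scrublet calls, and the enterochromaffin-like share, 17.1%, was 21.4% at 0.5, 21.7% at 2.0 and 21.9% with libraries alone. The INS ratio, −1.22, was −1.12 with median-of-ratios scaling, −1.29 as a mean of cells, −1.19 without hormone and mitochondrial genes in the totals and −1.28 without the top doublet scores. The cause of these moves was not tested. The double-positive share of D21, 22.9%, was 28.4% at a limit of 0.3% and 15.7% at 3%, which the limits bring about by construction. The beta-like share of D39 (10.1% to 11.03%), the maturation median (−0.86 to −0.60) and the secretion median (0.42 to 0.57) stayed within their intervals. Without cluster 21 the proliferation median of D32 over D21 went from 1.28 to −0.44, that of alpha-like cells at D39 over D14 from 2.75 to 0.84, and those of beta-like over alpha-like cells from −3.59 to −0.10 (−0.16 with the floor applied) at D32 and from −3.43 to −0.10 (0.04) at D39, since these few cycling cells hold most of the counts. Without cluster 0 that of pancreatic-progenitor-like cells at D14 over D11 turned from −1.54 to 1.41, and that of endocrine-progenitor-like over pancreatic-progenitor-like cells at D11 went from −5.51 to −1.72. Leaving out clusters 0 and 21 takes cycling cells from 1 side of each comparison only, which brings such moves about by construction. The 2 turned directions are of this kind, so they show where the counts lie and carry no direction. Scrublet removed 0 to 8 cells per library outside D11, so there its alternative is a new clustering and no check on doublets, and the 5 CPM filter removed no secretion gene. No paired analysis was possible because the labels carry no replicate numbers and no result comes from a test; the 3 libraries with both beta-like and enterochromaffin-like cells are different days.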

Other observations

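Several clusters stayed without a name, and the genes given for them were chosen after their values were seen. CPM values of a cluster are summed over all its cells, whichever library they come from. Cluster 7, 17.5% of D32 cells, held several hormones, with SST at 11545 CPM, GCG at 10835, INS at 15710 and TTR at 22003. Of its thinned cells 13.8% were SST-positive at D32 and 15.5% at D39, while 52.1% and 17.4% were INS-positive. Cluster 20, 36 cells of D32 and D39, carried genes of intestine and fetal liver: uroguanylin GUCA2B at 25319 CPM, guanylin GUCA2A at 2733, AFP at 5371 and the intestinal factor CDX2 at 91.4. Cluster 10, 10.0% of D21, had CDX2 at 80.5 and SOX9 at 139 CPM, with COL2A1, AGR2 and TFF3 among its top genes. Cluster 15, 17.8% of D21, scored best for enterochromaffin markers and still had the progenitor factor NEUROG3 at 113 CPM beside TPH1 at 1292 and NKX6-1 at 489. At D11, cluster 2 (25.8% of cells) had CHGA at 34112 CPM with INS at 434 and FEV at 578, and cluster 1 (21.3%) had TTR, FRZB and PRSS1 among its top genes. At D14, cluster 12 (33.2%) had INS at 8756 and FEV at 864 CPM. Clusters 5 of D11 and 14 of D14 held 7.55% and 6.70% of their libraries, both with 1.88 times the median UMIs, and median doublet scores of 0.248 and 0.215 against 0.0294 in cluster 16. They were taken as likely doublets, which was not tested further. Their cells were kept in the main shares and whole-library sums, and 94 of the 764 double-positive cells of D14 lay in cluster 14.

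The tests of the double-positive cells and of the immediate early genes were chosen after those results were seen, and so was the test of free RNA as the whole source of the secretion genes, while their other tests were chosen before. Cells positive for INS and GCG at D21 could be doublets or hold free hormone RNA; cluster 16, where most of them lie, had a median UMI total 1.05 times that of its library, which argues against doublets of full-sized cells. The double-positive cells themselves had a median of 26001 UMIs against 24039 in cells with INS without GCG, and 24 cells had GCG without INS against 694 with both, too few to pair up. Free RNA spread evenly would bring GCG near the limit in most cells. But 75.1% of D21 cells (73.5% to 76.6%) held GCG under 0.5% of their UMIs, which argues against it as the whole source of GCG. INS was not checked in this way. At D21 60.7% of cells were INS-positive. The share was 5.88% in cluster 10 (3.52% to 9.14%) and 18.6% in cluster 15, against 94.3% in cluster 16. Free INS RNA spread evenly would reach these clusters alike, so the gap argues against it as the whole source of INS in cluster 16. INS helped to form the clusters, so a part of that gap is built in. As a part of the source, free INS RNA stays open. The median cell still held 9 GCG UMIs against the limit of 55, so some free RNA stays open. That single cells make both hormones could hold and was not tested further.

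Immediate early genes higher at D32 than at D21 may reflect a different mix of cells, handling of the D32 cells, or the culture day. The lower of the medians within beta-like and enterochromaffin-like cells was 1.58, which argues against a different mix. The 2 medians differed by 0.0998, a shift shared by both classes that handling or culture day could equally give. With 1 library per day these cannot be told apart.

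Secretion genes higher in pancreatic-progenitor-like cells at D14 than at D11 may come from free RNA of endocrine cells or from a few endocrine cells placed in the class. Without the 41 of 947 cells that passed 1% in INS or GCG, counted on all their UMIs without thinning, the median was 2.66 against 2.80. This argues against a few hormone-rich cells as the source. Endocrine cells under that limit would stay in, and they were not tested. Of thinned D14 cells, only 14.5% of the endocrine-progenitor-like class and 33.2% of cluster 12 were positive for INS, GCG or SST. No INS UMI was found in 268 of 751 thinned cells, and free RNA spread evenly at the level this allows would bring a median of at most 21.6% of the secretion excess from any of 5 D14 source profiles, which argues against it as the whole source. As a part of the source it stays open. The median INS count of the class, 1 UMI, over the mean without INS-positive cells, 4.22 UMIs, was 0.237. The interval of that ratio, from 0.204 to 0.281, spans the bound of 0.25 set beforehand. The excess over D11 was also set against the level in all other D14 cells. It was 15.3% of that level for INS, 19.9% for GCG, 14.4% for CHGA and a median of 19.6% for secretion genes. Without the 41 hormone-rich cells these were 8.11%, 4.65%, 10.9% and 15.6%. Endocrine cells or their RNA in the class could give such shares, so they stay open as a source. A rise of these genes in progenitors themselves was not tested.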
